A study of Homo sapiens with 2 samples.

How the data were processed

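Total RNA from 2 cultures of the human gastric carcinoma cell line NCI-N87 was labelled with biotin and hybridised to the Affymetrix Human Transcriptome Array (HTA), a 1-colour array that covers coding and non-coding transcripts. One array held RNA of the parental line and the other RNA of a line resistant to T-DM1 (trastuzumab emtansine). The labels give no dose, no length of selection, no passage and no statement on whether the drug was present at harvest.

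The authors' deposited table holds log2 values for 70523 rows, of which most are transcript clusters (1 summarised value per annotated transcript locus) and the rest are control, background and other rows. Affymetrix Expression Console was used, per the submitters' processing notes; the algorithm, its version, the annotation version and the genome build are not given in the sources used here. The log base is likewise unstated and was taken as log2, the usual output of that program. The column medians were 4.76 on both arrays, and whether this comes from a normalization step is not given in the sources used here. Values reached 19.9 on each array, and 650 rows on the parental and 693 on the resistant array exceeded 16, the log2 ceiling of a 16-bit scanner, so the values are not plain log2 brightness and a difference of 1 need not be exactly a 2-fold difference in brightness. All folds given are on this deposited scale. The deposited values of 1681 rows, among them those of 772 genes, were identical on both arrays, and list medians of 0 come from such genes.

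Rows were named through the platform annotation, which lists 25324 of the rows: 23781 with 1 gene symbol and 1543 with several. The 45199 rows that the annotation table does not list are unnamed here. Symbols were brought up to date through the NCBI gene table for assembly GRCh38.p14: 21497 rows by gene identifier, 1974 by symbol and 306 by a synonym, with 4 left as given. No row with several symbols was assigned to a gene. Where a gene had several rows (528 genes), the one with the highest mean over both arrays was used, which left 22411 genes. The chromosome of a row was read from its own identifier and matched that of the gene table for 99.8% of 22273 genes. For subtracting chromosome medians, 120 genes on rows of alternative haplotypes took the chromosome in that row's name, and 84 genes without a chromosome, or on one not analysed, were left as they were. The gene table served only for names and for the order of neighbouring genes; no coordinates are printed because the build of the deposited rows is not given.

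With 1 array per group there is no test, no standard error and no p-value, and the number of arrays limits the precision of every value. The quantity reported is the resistant minus the parental value. A gene is called higher or lower when this difference is at least 1 on the log2 scale and the higher of its values is at or above 5.79, the median of the higher values over all genes (the floor). The table carries no detection calls, so the floor is a rule of this work and not a limit of detection. Of the 92 External RNA Controls Consortium (ERCC) rows, 75 lay under the floor on both arrays. Where the lower value of a gene lies under the floor, the fold is given as "at least", computed against the floor. The size rule itself uses the measured values, so such a bound can be under 2-fold. For 36 gene lists, the median difference of the measured members was set against 10000 random lists of the same size, each member drawn from genes in the same one of 20 bins of mean level. The percentile describes these 2 arrays and is not a test of the condition. Of the 725 distinct list members, 643 were measured under a single symbol.

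The lists, the size rule, the floor and the rule for the genes named were fixed before the data were examined. That rule takes the 12 protein-coding genes with the highest and the 12 with the lowest difference among called genes, up to 4 called members of each list with the largest difference (or, where none is called, the member at or above the floor with the largest), and 19 genes fixed in advance for their relation to the drug, its target or cell identity. Genes named outside this rule are marked as chosen after their values were seen. The chromosome analysis was added after the values were seen.

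Alternatives were median centring, quantile normalization and loess centring (span 0.3) of the arrays, the mean of a gene's rows, other floors (none, 75th percentile), other thresholds (1.5-fold, 4-fold), every row of the table, unmatched random lists, the mean of the members, members above the floor only, and each list without its most different member. Protein-coding genes only, and differences less the median of the gene's chromosome, were added later. On simulated arrays of 22411 genes with an SD of 0.3 between arrays, the size rule recovered 99.0% of 100 genes shifted by 1.5 and all of 100 shifted by 3.0, and passed 0.045% of unchanged genes. The percentile placed 3.0% of 100 unshifted lists outside the central 95% and all of 100 lists shifted by 0.5 above it. The simulated errors were independent between genes and narrower than the differences seen at or above the floor (median absolute difference 0.41). These rates may therefore be too favourable for the real arrays. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.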

Results

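Gene expression was measured on 2 arrays, 1 of parental NCI-N87 cells and 1 of a T-DM1-resistant line of the same cells. NCI-N87 is a gastric carcinoma line with amplified ERBB2, the gene of the receptor HER2. T-DM1 is an antibody-drug conjugate that links the HER2 antibody trastuzumab to the microtubule poison DM1, which is released after uptake and breakdown in lysosomes. The comparison asks how expression differs between the parental line and cells labelled as resistant to the drug. There were no replicates, so none of the differences below has been checked against variation between cultures, and all describe these arrays. Differences are resistant minus parental on the deposited log2 scale.

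Among called protein-coding genes, the largest differences in measured values involved a matrix protease, a stretch of chromosome 14 genes, a drug efflux pump and an organic anion transporter. MMP7, which encodes the secreted protease matrilysin, was 6.35 on the parental and 15.6 on the resistant array, a difference of 9.21. The other genes with the highest differences were PPP2R3C (7.62), BAZ1A (7.15), SRP54 (6.28), FAM177A1 (6.14), CYP2S1 (6.04), EAPP (5.73), PPP1R1B (5.68) and CFL2 (5.42), together with EMP3 (at least 93.0-fold), IQGAP2 (at least 46.4-fold) and ABCC2 (at least 19.8-fold), whose parental values lay under the floor. Among the lowest, SLCO1B3, an organic anion uptake transporter, was 13.2 on the parental and 4.24 on the resistant array, at least 171-fold lower. IVL, encoding the cornified envelope protein involucrin, was at least 97.6-fold lower, and DSG3, a desmosomal cadherin of squamous epithelium, at least 77.6-fold lower. CYP24A1 (-7.41) and CCN2 (-6.11) were measured above the floor on both arrays. The resistant values of the others lay under it, which gives at least 81.6-fold for A2ML1, 77.7-fold for TGFBI, 71.8-fold for CST7, 44.3-fold for CD109, 30.7-fold for LDHB, 25.8-fold for AGMO and 23.9-fold for ADGRL2. SLCO1B3 has close paralogues, so its row is uncertain as a measure of that gene alone.

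Over all 22411 genes, 1074 were called higher and 1022 lower on the resistant array, together 18.7% of the 11206 genes at or above the floor. The median absolute difference of genes at or above the floor was 0.41, and 56.8% of them differed by less than 0.5. Values correlated across genes with r = 0.964 (Pearson) and rho = 0.970 (Spearman); genes are not independent replicates. The hybridisation controls bioB, bioC, bioD and cre differed by at most 0.138 between the arrays, the poly-A controls lys, phe, thr and dap by at most 0.398, and 1 of 23 background rows by 1.45.

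**Figure D1:**
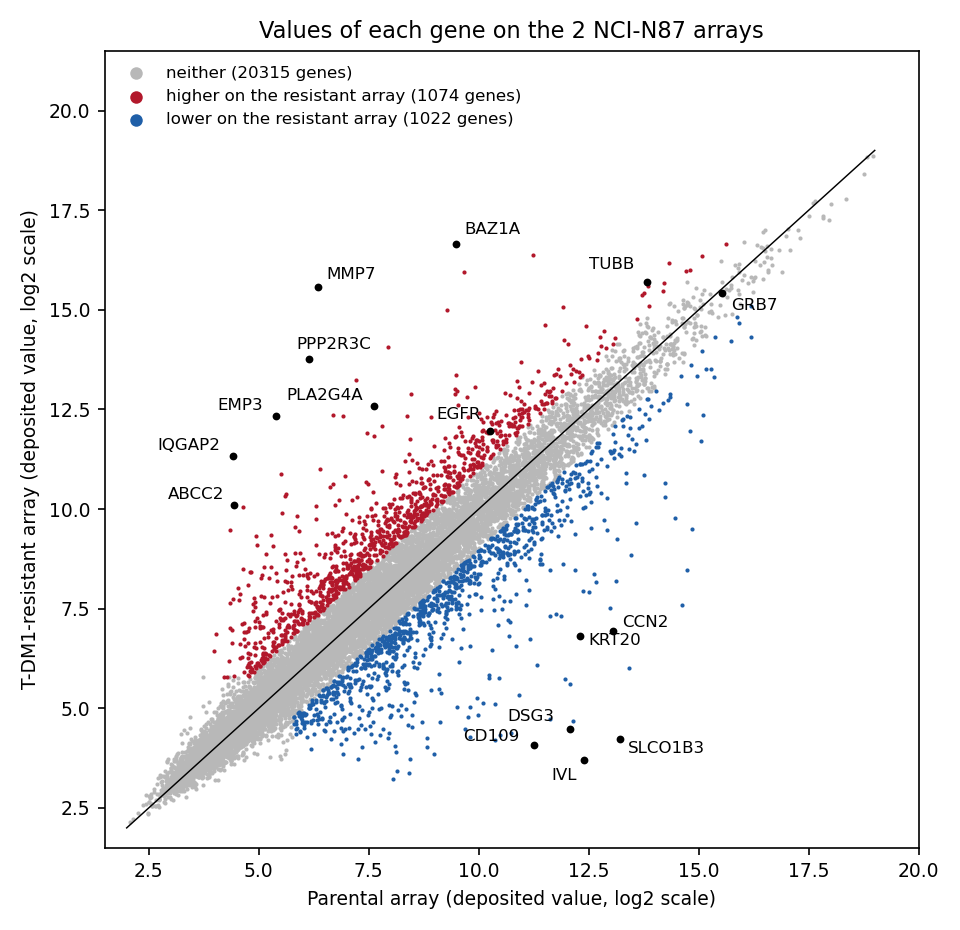
Each point is 1 of 22411 genes, with the deposited log2-scale value on the parental array (x axis) and on the resistant array (y axis), and the line marks equal values. Red and blue points are the 1074 genes called higher and the 1022 called lower on the resistant array; MMP7 lies far above the line and SLCO1B3 and IVL far below it.

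The row that includes the drug target was high on both arrays, and EGFR and a ligand were higher on the resistant array. The row annotated jointly to ERBB2 and the microRNA gene MIR4728, which cannot be assigned to either gene alone, was 16.99 on the parental and 16.44 on the resistant array, a difference of -0.54. GRB7, an adaptor gene amplified with ERBB2, was 15.5 and 15.4. ERBB3 differed by 0.32. EGFR was 10.3 and 11.9, a difference of 1.69 (1.07 less the median of its chromosome 7), and EREG, which encodes the EGFR ligand epiregulin, differed by 2.21, whereas TGFA, another EGFR ligand, differed by -1.27. Of 11 measured receptor family members and ligands, 2 were called higher, 1 lower and 8 neither, and the list's median difference was 0.06. Of 14 measured neighbours of ERBB2, 1 was called higher and none lower (median 0.004, at the 46.1 percentile of random lists). That gene was PPP1R1B, a phosphatase inhibitor gene, at 6.69 on the parental and 12.4 on the resistant array. Among 22 kinases and pathway genes, 8 were called higher and 2 lower, with a median of 0.34 at the 99.5 percentile. MTOR (1.85), AXL (1.68) and FGFR3 (at least 2.76-fold) were higher, and DUSP6, a phosphatase gene induced by ERK signalling, was lower (-2.88).

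Genes tied to uptake, lysosomal breakdown and efflux of the drug differed in both directions. The efflux pump genes ABCC2 (at least 19.8-fold), ABCG2 (at least 2.56-fold) and ABCC1 (3.03-fold) were higher on the resistant array, and ABCC5 was lower (-1.51); ABCB1, which encodes P-glycoprotein, lay under the floor on both arrays (3.84 and 4.06). Of 11 ABC transporters measured, 3 were called higher, 1 lower and 7 neither, and the median of 0.27 lay at the 96.81 percentile, within the central 95% of random lists but outside it under 4 of the 8 alternatives that give a percentile. Of 24 measured subunits and accessory proteins of the vacuolar ATPase, the pump that acidifies lysosomes, none was called higher, 2 were called lower and 22 neither. The lower ones were ATP6V1C2 (at least 1.96-fold) and ATP6AP2 (-1.02), which was between -0.98 and -0.95, under the size rule, with quantile normalization, loess centring or less the chromosome median. The list's median was -0.23, at the 1.9 percentile of random lists, but without ATP6V1C2 it was -0.09 at the 16.9 percentile. Of 25 lysosomal genes, 5 were called higher and 4 lower (median -0.13, 16.5 percentile). GLA (2.40), TPP1 (2.00) and GUSB (1.89) were higher. The called cathepsin protease genes went both ways. CTSS (-2.33) and CTSB (-1.63) were lower, and CTSC (1.49) and CTSH (1.53) were higher. CTSB, CTSC and CTSH were chosen after their values were seen. LAMP1, a lysosomal membrane glycoprotein gene, differed by -1.07. SLC46A3, which encodes a lysosomal transporter of maytansinoid catabolites, differed by -0.97 but lay under the floor on both arrays (5.48 and 4.52). LAMP1 and SLC46A3 are both on chromosome 13, whose genes had a median difference of -1.09. Of 22 endocytosis genes, 1 was called higher (FLOT1, 1.73, or 0.97 with the mean of its 8 rows, under the size rule) and 3 lower: CAV1 (at least 1.99-fold) and CAVIN1 (-1.31), which encode caveolar coat proteins, and CLTA (-1.12), a clathrin light chain gene. RAB5A differed by -0.73.

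Tubulin genes and genes of glutathione and xenobiotic metabolism had mostly positive differences. DM1 binds tubulin. Of 18 tubulins and microtubule-associated proteins, 6 were called higher, 1 lower and 11 neither; 17 of the 18 had a positive difference, and the median of 0.80 lay above all 10000 random lists. TUBB (1.87), TUBG1 (1.65) and TUBB2A (1.51) were higher and MAP7 was lower (-1.36, or -0.92 less the median of its chromosome 6). The 2 parts of chromosome 6 differed. TUBB2B (1.23, called higher, chosen after its values were seen) lies in the same part as TUBB and TUBB2A. Genes of that part had a median of 0.55, and those of the part with MAP7 -0.92. Subtracting the median of the whole chromosome (-0.44) therefore raised TUBB and TUBB2A, and corrected MAP7 by less than the median of its part. The list's median less chromosome medians (0.81) is thus no check on a shift of the part with TUBB, whose own median was not subtracted. Beta-tubulin genes are near-identical over much of their length, so their rows may share signal. The row annotated jointly to TUBB3 and MC1R was under the floor on both arrays (5.53 and 5.48). Of 24 glutathione and xenobiotic genes, 9 were called higher and 3 lower (median 0.49, also above all random lists), with GSTM3 (at least 3.99-fold), GSTK1 (2.23) and the glutathione peroxidase gene GPX2 (1.82) higher and CYP1B1 (-1.74) lower.

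Cell division genes had the highest median differences of the 36 lists. Of 24 mitosis and spindle checkpoint genes, 23 were called higher and none lower, with a median difference of 1.55, and of 24 DNA replication genes, 19 were called higher and none lower, with a median of 1.54. Both medians lay above all 10000 random lists. KIF20A (2.38) and KIF23 (2.17), kinesin genes of cytokinesis, CENPF (2.12) and DLGAP5 (1.83) led the first list, and TYMS (2.70), which encodes thymidylate synthase, PCNA (2.21), MCM10 (2.08) and MCM6 (1.91) the second. Only TTK (-0.10) and RFC3 (-0.84), chosen after their values were seen, had negative differences among these 48 genes. TTK lies in a part of chromosome 6 whose genes had a median of -0.92. RFC3 lies on chromosome 13, whose genes had a median of -1.09. The 10 measured housekeeping genes also had a positive median, 0.47 at the 97.52 percentile, within the central 95% under 7 of 9 alternatives; ACTB differed by 0.16 (-0.45 less the median of its chromosome 7) and GAPDH by 0.30. Of 14 p53 target genes, GDF15 (-2.42) and TP53INP1 (-2.28) were lower and AEN (1.07) higher. Of 18 apoptosis genes of the BCL2 family and death receptor pathway, 1 was called, BCL2 (1.20).

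Junction and keratin genes were called lower more often than higher, and integrins and laminins about as often each way. No mesenchymal gene at or above the floor was called higher. Of 22 junction and keratin genes, 1 was called higher and 6 lower (median -0.43, 0.7 percentile; without KRT20 -0.295 at the 5.4 percentile, within the central 95%). KRT20 was lower (-5.49), as were DSP (-1.82), ESRP2 (-1.52) and CDH1 (-1.10), the E-cadherin gene, and CLDN3 was higher (3.88). Of 21 mesenchymal genes none was called higher and 1 lower, TGFBI. Only 7 of the 21 lay at or above the floor, and the others could not be called. VIM was among those under the floor on both arrays (4.54 and 4.82). Of 14 integrins and laminins, 3 were called higher and 4 lower. ITGB6 (at least 24.0-fold), ITGA1 (at least 6.05-fold) and ITGA3 (-1.72) were lower and LAMB1 (2.52) higher; the median of -0.37 lay at the 2.4 percentile but within the central 95% under 7 of 9 alternatives. Lineage genes split. MUC1 (at least 17.3-fold), the intestinal mucin gene MUC13 (4.62) and VIL1 (at least 11.6-fold), encoding villin, were higher, and CEACAM6 (-4.69) and CEACAM5 (-4.55), which are paralogues, were lower. Of 18 gastric genes 3 were called higher (MUC1, CTSE by at least 2.99-fold and GATA6 by 1.12) and 1 lower (GATA4, at least 2.17-fold). Of 22 intestinal genes 3 were called higher and 3 lower (median 0.15, 99.5 percentile, within the central 95% under 3 of the 8 alternatives that give a percentile). Only 6 of the 22 lay at or above the floor, so this median comes from genes under it.

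Interferon response genes had mostly negative differences, and antigen presentation genes differed individually. Of 29 interferon genes, 1 was called higher and 6 lower, and 21 had a negative difference (median -0.59, 0.01 percentile). The RNA sensor gene RIGI (-2.85), OAS2 (-2.63) and MX2 (-1.61) were lower, and HERC5 was higher (2.08). Of 19 antigen presentation genes 3 were called higher, HLA-DRA (3.73), CD74 (2.31) and HLA-DMA (1.29), and 1 lower, the peptide transporter gene TAP1 (-1.39). The list's median was 0. HLA-DRB1 (0.31) and CIITA (0.85), class II genes chosen after their values were seen, were not called. The prostaglandin list held PLA2G4A (4.96), encoding the phospholipase that releases arachidonic acid, PTGS2 (2.30), encoding cyclooxygenase-2, and HPGD (at least 2.33-fold) as higher, and PTGER2 (-1.65) as lower; its median was 0.06. The 22 NF-kB and cytokine genes held 4 called higher, among them NFKBIZ (1.73), CXCL2 (1.41) and ICAM1 (1.31), and 2 lower, among them IL1RN (at least 2.72-fold).

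Targets of developmental pathways differed individually. Of 15 YAP targets 1 was called higher and 4 lower: CCN2, NT5E (-4.93) and F3 (-4.43) were among the lower ones and AXL was higher (median -0.28, 7.3 percentile; mean -1.09). Of 19 TGF-beta and BMP genes 5 were called higher and 4 lower; SKIL (-2.84) and ID1 (-2.77) were lower and BAMBI (1.91) higher, with a median of 0.23 and a mean of opposite sign (-0.27). The median lay at the 97.485 percentile, within the central 95% but outside it under 5 of 9 alternatives. Of 19 Wnt genes 4 were called higher and 3 lower (median 0.11, 87.1 percentile); the antagonist gene DKK1 (3.86) and NKD1 (2.23) were higher and WNT11 (-2.59) and FZD7 (-1.35) lower. Sterol and lipid genes (5 of 17 called higher, 1 lower, median 0.52, 99.5 percentile) lay within the central 95% without HMGCS1 (0.34, 96.7 percentile) and once chromosome medians were subtracted (0.24, 94.7 percentile). They included HMGCS1 (2.34), INSIG1 (1.94) and SCD (1.85) as higher and STARD4 (-2.03) as lower. Of 20 hypoxia and glycolysis genes 7 were called higher and none lower (median 0.46, 99.8 percentile): EGLN3 (at least 6.15-fold), SLC2A3 (1.62) and ENO1 (1.56) were among them, with ENO2. EGLN3 lies in the chromosome 14 stretch described below. Of 18 respiratory chain genes 2 were called higher, CYCS (1.503, or 0.88 less the median of its chromosome 7, under the size rule) and UQCRC1 (1.28), with a median of 0.35 at the 97.66 percentile, within the central 95% under 6 of 9 alternatives. Of 17 heat shock and immediate early genes 2 were called higher and 3 lower (median 0.11, 76.5 percentile), and of 20 unfolded protein response genes 1 was called higher and 3 lower (median -0.16, 15.3 percentile). Of both lists, JUNB (-3.58), IER2 (-1.98), DNAJB1 (-1.51), EDEM1 (-1.98), CHAC1 (-1.96) and HERPUD1 (-1.21) were lower, and JUN (1.698) and PDIA4 (1.76) higher. Of 13 ribosomal protein genes, RPS6 was called lower (-1.06, or -0.95 less the median of its chromosome 9, under the size rule) and none higher (median -0.26, 12.96 percentile).

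Markers of other cell types were mostly under the floor. Of 18 immune markers, 1 was called, LYZ (1.52), and PTPRC, chosen after its values were seen, lay under the floor (4.06 on both arrays). None of 15 fibroblast and endothelial markers was called; ESAM differed by 0.32. SERPINA1 (-2.25) was the only called gene among 9 erythroid and hepatocyte markers. Of 12 neuroendocrine and squamous markers, ENO2 was called higher and IVL, KRT14 and NCAM1 lower. The resistant values of KRT14 and NCAM1 lay under the floor, and against it they were at least 1.61-fold and 1.01-fold lower, under the 2-fold of the size rule. The list lay below the central 95% (median -0.18, 2.48 percentile), and without IVL its median was 0.064 at the 66.5 percentile. In all, 10 of the 36 lists lay above and 5 below the central 95% of random lists. Lists drawn gene by gene at random would place 1.8 outside it. Members of a real list can vary together, so 1.8 is not the number to expect between 2 cultures without resistance. The 10 include the housekeeping list, and the intestinal list, whose median comes from genes under the floor. Neighbouring genes and shared members make lists dependent.

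**Figure D2:**
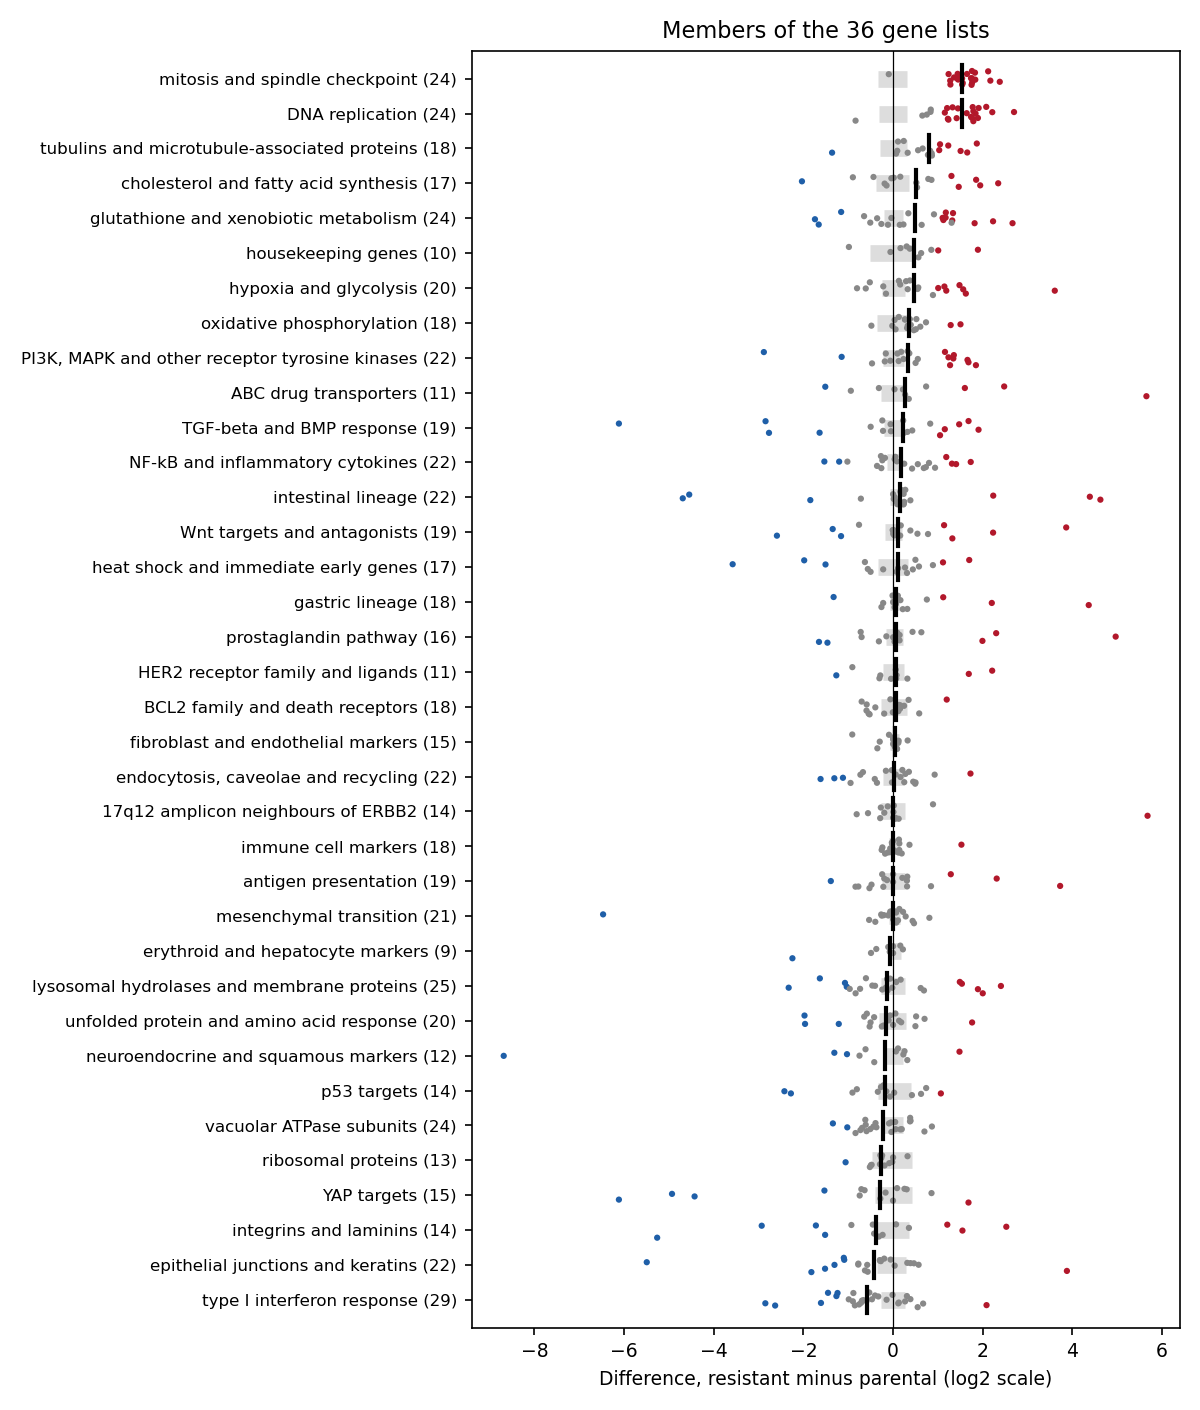
Rows are the 36 gene lists with the number of measured members, ordered by median; the x axis is the difference, resistant minus parental, on the log2 scale. Points are genes (red called higher, blue called lower, grey neither), black bars are medians and grey bands the central 95% of medians of 10000 random lists matched on level; the mitosis and DNA replication medians (1.55 and 1.54) lie far to the right of their bands.

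Differences also followed chromosomes. Chromosomes were examined after the values were seen, over 9755 protein-coding genes at or above the floor. The 164 genes of chromosome 13 had a median difference of -1.09 (quartiles -1.55 and -0.47), with 88 at -1 or below and 3 at 1 or above. The 450 genes of chromosome 7, which include EGFR and CLDN3, had a median of 0.62, with 114 at 1 or above and 13 at -1 or below. The 466 genes of chromosome 6, which include CCN2 and NT5E, had a median of -0.44 and the widest quartile range of all chromosomes (-1.27 to 0.41). Split in gene order where the gap of medians, weighted by the sizes of both parts, was widest, the 167 genes from one end up to KCNK5 had a median of 0.55 and the 299 from OARD1 onward -0.92. TAP1, HLA-DRA, HLA-DMA, FLOT1, DSP, TUBB and TUBB2A lie in the first part, and CCN2, NT5E, CD109 and MAP7 in the second. The other chromosomes analysed had medians between -0.11 and 0.22. On chromosome 14, 19 adjacent genes from G2E3 to PRORP had differences from 1.28 to 7.62, with a median of 3.61. The other 302 genes of that chromosome had a median of -0.06. The stretch was extended from the centre of the highest window of 7 adjacent genes while the next gene differed by 1 or more. That all its genes were higher therefore follows from this rule. PPP2R3C, BAZ1A, SRP54, FAM177A1, EAPP and CFL2, which are among the 12 genes with the highest differences, lie in this stretch. The parental values of COCH, AKAP6 and EGLN3 lay under the floor. COCH gave the lowest difference of the stretch (1.28) and EGLN3 the median one (3.61, at least 6.15-fold against the floor). Adjacent here means next to each other among the analysed genes. The next such gene beyond PRORP, PSMA6, differed by 0.502. G2E3, COCH, AKAP6, PRORP, PSMA6, KCNK5 and OARD1 were named after their values were seen.

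**Figure D3:**
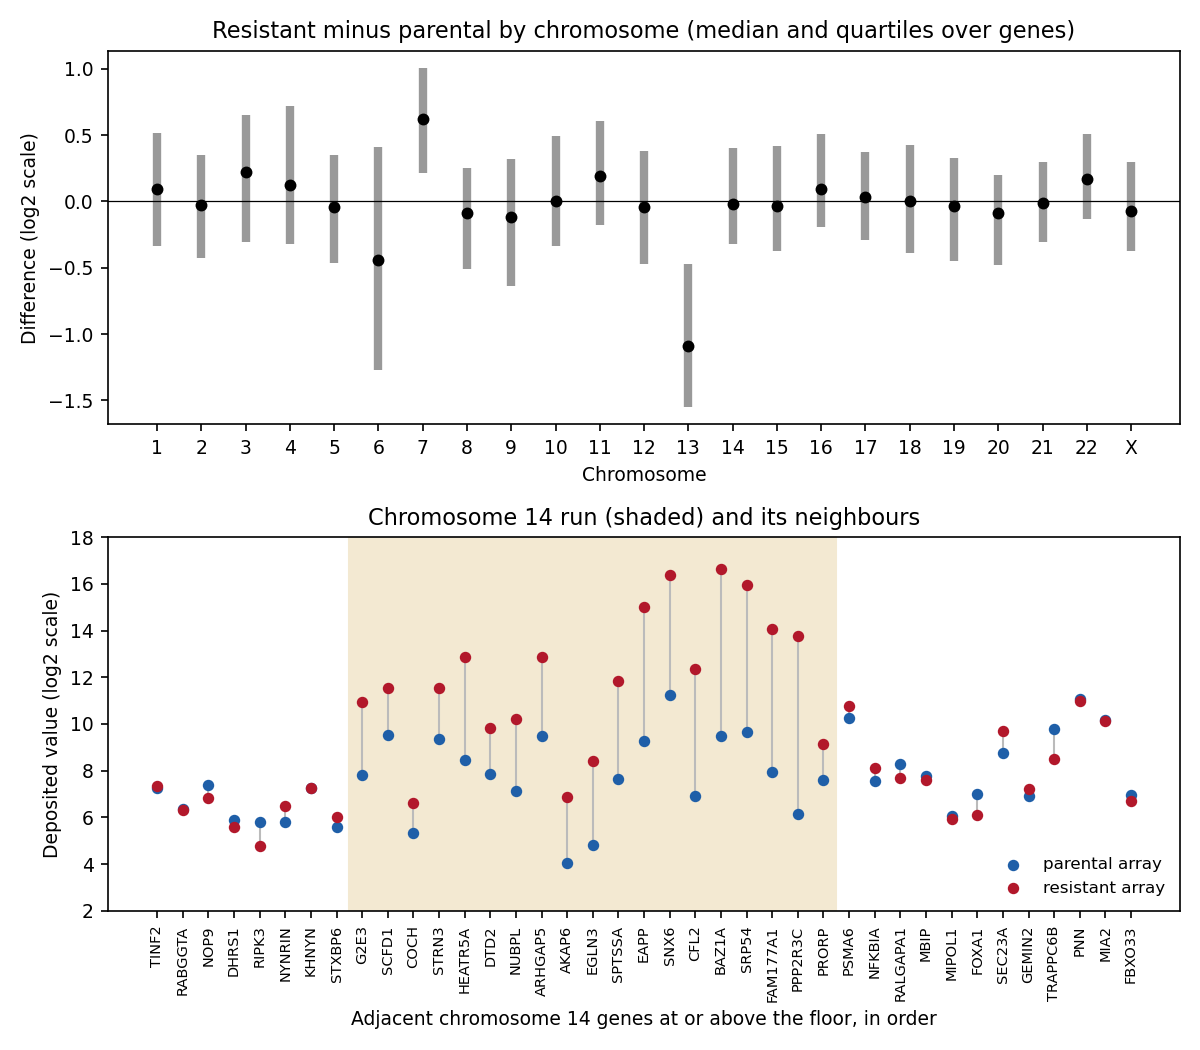
Top: median (point) and quartiles (bar) of the difference, resistant minus parental (log2 scale), over protein-coding genes at or above the floor on each chromosome; chromosome 13 is lowest at -1.09 and chromosome 7 highest at 0.62. Bottom: deposited log2-scale values of adjacent chromosome 14 genes in order on the parental (blue) and resistant (red) arrays. The 19 genes of the stretch are shaded, and each red point there lies above its blue point, as the rule that bounds the stretch requires.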

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

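Values that the comparison of named genes leaves out differed as widely as those it uses; all were picked after the data were seen. Among unnamed transcript clusters, the highest difference belonged to a chromosome 7 row (TC07001168.hg.1), at 6.24 on the parental and 16.57 on the resistant array, a difference of 10.33. The lowest belonged to a chromosome 12 row (TC12002282.hg.1), at 15.60 and 4.27, a difference of -11.33. Of 9744 unnamed clusters at or above the floor, 518 were higher and 1129 lower on the resistant array by the size rule. Of 818 rows with several gene symbols at or above the floor, 74 were higher and 40 lower. Of 1343 numbered rows with no annotation used here, 418 differed by 1 or more in either direction. With 1 array per group, no array could be examined as an outlier of its group.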

How the results depend on the processing

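The settings that use protein-coding genes only or subtract chromosome medians were chosen after the results were seen. Counts stayed within 1.5 times those reported under median centring, quantile normalization, loess centring, the mean of a gene's rows, no floor, and both later settings. A floor at the 75th percentile gave 640 lower genes, a 4-fold threshold 234 higher and 251 lower, a 1.5-fold threshold 2166 and 2016, and every row 2227 and 2626, as follows from fewer or more values passing. List medians moved by less than 0.31, the robust SD of differences over genes, in 311 cases, and by more in 12. Another, of a list outside the central 95% of random lists, turned its sign. Many of the 311 could not move by more. Unmatched random lists leave a median unchanged, median centring shifts every gene by 0.025, and the largest loess correction was 0.17. Values of 7 lists inside the central 95% also turned in 22 cases, among them TGF-beta genes (-0.27), heat shock genes (-0.18) and endocytosis genes (-0.09) with the mean, and lysosomal genes (0.020) less the chromosome median. With the mean in place of the median, the neighbours of ERBB2 gave 0.33, ABC transporters 0.78, gastric genes 0.43, TGF-beta genes -0.27, YAP targets -1.09 and neuroendocrine and squamous markers -0.86. With members above the floor only, gastric genes (4 left) gave 1.66, NF-kB genes 0.73 and prostaglandin genes 0.43. Erythroid and hepatocyte markers gave -2.25, which is the value of SERPINA1, the 1 member left. Neuroendocrine and squamous markers (6 left) gave -0.89. In this setting 9 lists were too short for a percentile. Without IVL but with all its other members, the neuroendocrine and squamous list gave 0.064. Antigen presentation genes gave 0.439 less the chromosome median, which is the chromosome 6 median of -0.44 taken from genes identical on both arrays. The correction has the wrong sign for the part with a median of 0.55, which holds 15 members (TAP1 included), TUBB, TUBB2A and DSP. The kinase, tubulin, glutathione, mitosis, DNA replication, interferon and hypoxia lists lay outside the central 95% of random lists on the same side under all 9 alternatives, the junction list under 8, vacuolar ATPase and sterol lists under 7, respiratory chain under 3, housekeeping and integrins under 2. With members above the floor only, the intestinal and the neuroendocrine and squamous lists were too short for a percentile; they kept their side under 5 and 4 of the other 8. Of the lists inside it, TGF-beta genes lay outside under 5 alternatives, ABC transporters under 4, YAP targets and unfolded protein genes under 2, and 9 further lists under 1; the cause was not tested. Differences of named genes moved by less than 0.31 in 674 cases and by more in 25. Under median and loess centring they could not move by more. LAMP1, called lower, was 0.020 once the chromosome 13 median was subtracted, and of the genes not called SLC46A3 (0.13), ABCB1 (-0.40) and ACTB (-0.45) turned in this setting. Of the 131 named genes called, 7 lost the call less the chromosome median: LAMP1, CYCS (0.88), MAP7 (-0.92), TAP1 (-0.95), ATP6AP2 (-0.95), RPS6 (-0.95) and NCAM1, whose higher value no longer reached the floor. ATP6AP2, NCAM1 and PGK1 lost it under quantile normalization, ATP6AP2 under loess centring, PGK1 under median centring and FLOT1 (0.97) with the mean of its rows. No paired analysis was possible because each group holds 1 array. Signal over background limits low values: 32 of the 140 genes named by the rule had their lower value under the floor.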

Other observations

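The tests of single-row errors on chromosome 14, of level-dependent scaling on chromosome 13, and of level-dependent scaling and housekeeping genes for cell division were chosen after the results were seen.

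The chromosome 14 stretch of 19 adjacent genes had a median difference of 3.61. Scaling is argued against by a lowest median of 3.57 under centring, quantile and loess scaling. This rests on the small trend over all genes (largest loess correction 0.17), and the rescaled value gives no separate evidence. Row errors that do not depend on position are argued against by a highest running median of 7 adjacent genes of 6.14. The highest in 1000 shuffles of gene order was 2.82. More copies of the stretch in the resistant cells are a candidate explanation, and the design of the annotated probes another. Both arrays carry the same probes, so probe design alone gives no difference. It could only spread a difference of some genes over the rows of others (cross-hybridisation). The 9 unnamed rows placed inside the stretch by their row numbers had a median of 0.048 (quartiles -0.27 and 2.48, with 4 at 1 or more), under the 0.5 set beforehand as counting against more copies and for probe design. A condition on the quartiles, added after these values were seen, leaves both explanations open. Of the 9 rows, 6 were placed less surely, in a block whose numbers followed gene order with rho = 0.793. The other 3 (rho = 1.0) had the same median (-1.01 to 3.43, with 1 at 1 or more). DNA copy number was not analysed here. Unnamed rows also differed less than named genes on chromosome 7 (medians 0.15 and 0.62) and chromosome 13 (-0.34 and -1.09). The cut of 0.5 therefore cannot decide between the explanations.

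On chromosome 13 the median was -1.13 after loess centring, and 73.8% of its genes lay at -0.5 or below. What argues against level-dependent scaling is the small trend over all genes (largest loess correction 0.17). With a correction of that size, the median after centring gives no separate evidence. Fewer copies of the chromosome in the resistant cells may explain the pattern. The 172 unnamed rows of chromosome 13 had a median of -0.34, under the -0.20 that bounds the lowest 2.5% of random sets of unnamed rows but above the -0.5 set beforehand for fewer copies, so this stays open.

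The 48 cell division genes had a pooled median of 1.55, which was 1.58 after loess centring and 1.47 less each gene's chromosome median. These values argue against level-dependent scaling and shifts of whole chromosomes as the whole cause. For scaling this rests only on the small trend over all genes, where the largest loess correction was 0.17. The excess over housekeeping genes was 1.08 (bootstrap interval over genes 0.69 to 1.51, a condition added after the excess was seen). That interval treats genes as independent and holds no variation between cultures. For these 2 arrays only, the excess argues against a general difference in genes shared by all cells as the whole cause. A growth difference that comes with resistance, or a difference in density or feeding of the cultures at harvest, could give this pattern; neither was tested, and 1 culture per line leaves them together.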
